A study of Mus with 2 samples.

How the data were processed

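Kidney cells of young and of senescent C57BL/6 mice were profiled by droplet single-cell RNA sequencing, with 1 library per group and 2 libraries in all. Per the submitters' processing notes, reads were processed with Cell Ranger 2.1.1 and the genome build was mm10. Per the labels' protocols, tissue was digested enzymatically and cells were counted after trypan blue staining. The filters on cells, the treatment of doublets and free RNA, the clustering, and the test behind the comparison were not given in the sources used here.

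The authors' deposited table compares the libraries within 7 clusters. Its columns for the groups hold a signal that the authors averaged over the cells of a cluster. It is never negative, its scale factor is not stated, and the listed young values of a cluster sum to between 2876 and 8661. The columns were assigned to the libraries by the descriptions that the labels give. The table's own name for the contrast sets C57 against WT with a numeric code, is not explained in the sources used here and names neither group as young or senescent, so the direction of every fold change rests on those descriptions. The log2 fold changes in the deposited table equal the log2 of the senescent over the young mean after adding 0.0001 to each, within 0.01, in every row but 1 (Cfi in PT, 5.37 in the authors' deposited table and 5.94 by the formula). The p-value column of the deposited table holds only values under 0.05. The adjusted p-values in the authors' deposited table are headed as a false discovery rate, but where they could be compared they equal the p-value times about 32568, as a Bonferroni adjustment would give. Depth is unknown, so no counting interval was computed.

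Computed here were counts of genes past the authors' adjusted p of 0.05 and absolute log2 fold change of 1, ratios of the means, and medians of fixed gene lists. List medians used the log2 ratio of the means after adding a pseudocount of 1, which understates the change of low genes, over members with a mean of at least 0.1 in the higher library, and needed 5 members. The percentile of each median was taken among 10000 random lists of the same size drawn from the listed genes of that cluster in 10 bins of mean expression. It describes these libraries and is not a test. A median was obtained for 105 pairs of a list and a cluster, of which 28 lay above percentile 97.5 and 35 below percentile 2.5. The 19 marker lists and 20 functional lists were fixed before the data were examined. No test between groups was run, since each group had 1 library. The procedure was run on simulated data for PT with 5037 genes. In these, 95.5% of 200 changed genes were recovered at a simulated log2 change of 1.5. Of 100 lists without a change, 5 fell outside percentiles 2.5 to 97.5. Both values follow from the settings of the simulation and check the code only. Every simulated gene passed the adjusted p, the noise was symmetric and independent between genes, and the unchanged lists were random draws.

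The rule for named genes, set before the data were examined, took in each cluster the 3 genes with the largest log2 fold change in each direction and, from each list, up to 4 members with the largest value, with an adjusted p of at most 0.05 and a mean of at least 0.1 in the higher library. S100a8 and S100a9 in Neutro, the genes named as higher in all 6 clusters other than Neutro (Igkc, S100a9, Apoe and H2-Eb1), and in the closing part Cyp2e1, Cyp2a4, Timd2 and the nuclear and Y-linked genes fall outside this rule in some or all clusters and were chosen after their values were seen. The planned analyses of UMI counts per cell, of cell shares and of cluster identities were not run, because the values analysed were means per cluster. Gene symbols were matched to the mouse reference annotation for 8107 genes (99.0%), which has the same build. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Alternatives tried were other thresholds on the adjusted p, the fold change and the mean, other pseudocounts, no filter on low values and, chosen after seeing the data, no adjusted p, removal of genes with higher means in PT, and the log2 fold changes of the authors.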

Results

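Single-cell RNA sequencing was performed on whole-kidney cell suspensions from young and from senescent C57BL/6 mice, with 1 droplet library per group. The series states 10895 cells for the young mice and 4408 for the senescent mice. The values analysed were the authors' means of scaled expression per cell in 7 clusters, which they labelled PT, LOH, endo, Marco, T, B and Neutro. These labels are kept here as given. The authors' deposited table held 20111 entries for 8191 distinct genes, and it lists a gene in a cluster only where the p-value was under 0.05 and the absolute log2 fold change was at least 0.36. A gene that is not listed can therefore not be called unchanged. With 1 library per group there was no spread between mice to test against, so each value below is a mean of 1 library without SD, and adjusted p-values in the authors' deposited table measure spread between cells. The number of cells per cluster, the sequencing depth, the number of mice per library and their ages were not given in the sources used here.

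The comparison that the design implies is that of senescent with young kidney within each cluster. In the authors' deposited table, 2881 genes were higher and 282 lower in the senescent library in PT, at an adjusted p of at most 0.05 and an absolute log2 fold change of at least 1. For Marco the authors' deposited table gave 1020 higher and 1051 lower genes. For T the authors' deposited table gave 168 higher and 903 lower genes, for B 86 and 477, for LOH 38 and 121, and for endo 4 and 6. These counts do not rank the clusters by size of change. An adjusted p over cells depends on the number of cells in a cluster, which was not given. The adjusted p was passed by 5035 of 5037 listed genes in PT and by 10 of 1028 in endo. No gene of Neutro passed the adjusted p in the authors' deposited table, which listed 24 higher and 354 lower genes there. Among these the smallest mean above 0 was 1.07 in the young and 0.00475 in the senescent library. The excess of lower genes in Neutro may therefore reflect this high floor of the young means.

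**Figure D1:**
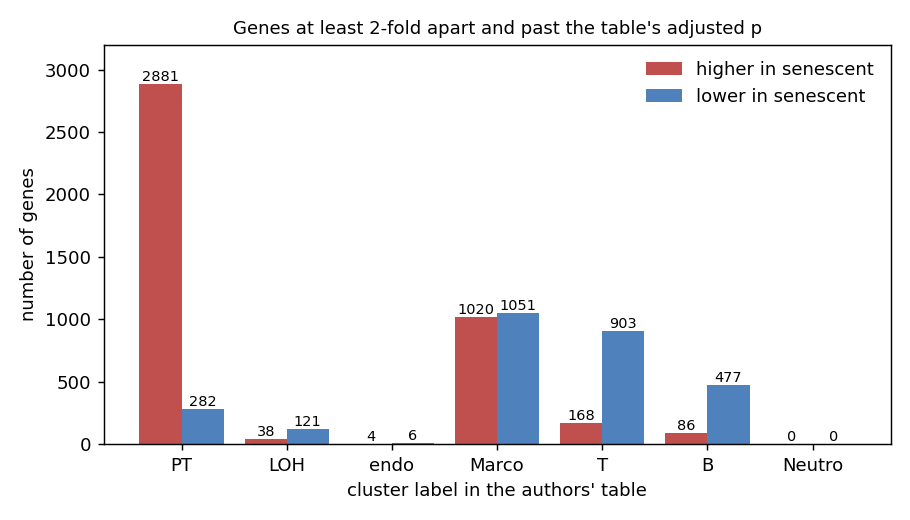
Number of genes (vertical axis) higher or lower in the senescent library in each of the 7 clusters (horizontal axis), at an adjusted p of at most 0.05 and an absolute log2 fold change of at least 1 in the authors' deposited table. PT had 2881 higher and 282 lower genes, and T had 168 higher and 903 lower genes. The counts depend on the number of cells per cluster, which was not given, and do not rank the clusters by size of change.

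In the PT cluster, most listed genes of the tubular injury list were higher in the senescent library, whereas respiratory chain genes and several androgen-dependent genes were lower. Spp1, which encodes osteopontin, had a mean of 2.62 in the young and 62.4 in the senescent library, a 23.8-fold difference. Cxcl1, a neutrophil-attracting chemokine, went from 0.00565 to 0.644, the complement component C3 from 0.0264 to 1.24, and ceruloplasmin, encoded by Cp, from 0.00849 to 0.606. Of the 8 listed members of the tubular injury list, 7 were higher and 1 was lower, and their median log2 ratio of 0.61 lay above all 10000 random lists. The other 12 of the 20 members were not listed in PT. Of the 13 markers of parietal or injured epithelium, only Spp1 and Cp were listed there. The injury markers Havcr1, Lcn2, Krt20, Vcam1 and Sox9 were thus not listed in PT. In PT 78.4% of all listed genes were higher. Among genes of senescence and cell-cycle arrest, 7 of 8 listed members were higher, with a median at percentile 97.25, just inside the central 95% of random lists. They included Gdf15, a stress-induced cytokine, at 0.476 and 6.47, and Cdkn1a, which encodes the cell-cycle inhibitor p21, at 0.0303 and 0.333. Of the genes with the largest fold changes, Ugt1a2, a glucuronosyltransferase, had means of 0.000253 and 0.440, and Serpina10 had means of 0.00379 and 0.437. The largest fold changes downwards in PT were in Gm48281 (0.645 and 0.00239), the proton pump subunit gene Atp6v1g3 (0.510 and 0.00342) and the organic anion transporter gene Slc22a7 (1.43 and 0.0126). The young mean of Ugt1a2 and the senescent mean of Gm48281 were the smallest listed in PT, so the size of their fold changes is uncertain. Atp6v1g3 is also a marker of intercalated cells, and markers of other cell types were lower in PT as well. All 3 listed markers of the thick ascending limb were lower, with Umod at 3.20 and 0.535 and Ppp1r1a at 1.13 and 0.0269, as were Slc12a3 of the distal convoluted tubule (0.341 and 0.108) and all 3 listed haemoglobin genes.

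Nuclear-encoded genes of oxidative phosphorylation were lower in 40 and higher in 1 of 41 listed members in PT, with a median log2 ratio of -0.83 that lay below all 10000 random lists. Ndufb2, of respiratory complex I, had means of 9.45 and 3.46, and Uqcrq, of complex III, had means of 22.6 and 8.94. Genes of the mitochondrial genome were lower in 6 and higher in 3 of 9 listed members. Of 20 listed genes of fatty acid oxidation and peroxisomes, 14 were higher, a share below that of all listed genes in PT, among them Pdk4 (0.0490 and 2.57), an inhibitor of pyruvate dehydrogenase, and Cyp4a14 (0.360 and 5.07). Their median log2 ratio of 0.43 was at percentile 92.6, inside the range of random lists. Markers of the proximal tubule itself were lower in 10 and higher in 6 of 16 listed members in PT, with a median of -0.45 at percentile 37.6. Solute transporters of the proximal tubule went both ways, with 16 higher and 9 lower, a share of higher genes below that of all listed genes in PT. The sulfate transporter gene Slc13a1 was 11.0-fold higher, at 1.48 and 16.3, and the bicarbonate transporter gene Slc4a4 was 4.23-fold higher, at 2.78 and 11.8. All 25 listed genes of cytosolic ribosomal proteins were higher, at percentile 99.9. All 9 listed genes of MHC class I and II were also higher, with B2m at 0.942 and 5.38, but their median was at percentile 77.8, inside the range of random lists.

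Genes known to depend on sex in the mouse kidney also differed in PT. Kap, an androgen-induced gene that was the most abundant of the list in the young library, had means of 719 and 21.4, a 33.6-fold difference. Acsm3 was 69.1-fold lower (1.49 and 0.0215), and Prlr, the prolactin receptor gene, was 90.3-fold higher (0.0252 and 2.27). Immediate early genes, which respond to tissue dissociation as well as to stress, were higher in 15 and lower in 4 of 19 listed members. That share of higher genes was close to the 78.4% of all listed genes in PT. Fos had means of 0.0598 and 3.35, and Fosb had means of 0.0191 and 1.71. The median log2 ratio of that list was 0.56, at percentile 99.97.

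In the LOH cluster, Umod, which encodes uromodulin of the thick ascending limb, was 3.11-fold higher in the senescent library, at 47.6 and 148. Spp1 was 7.71-fold higher, at 13.1 and 101, and Lcn2, a marker of tubular injury, was 25.4-fold higher, at 0.128 and 3.26. All 5 listed markers of parietal or injured epithelium were higher, with a median log2 ratio of 1.03, and they included Sox4 (0.485 and 1.71). All 8 listed MHC genes had higher means, with Cd74 at 0.213 and 2.44, and 3 of them passed the adjusted p in the authors' deposited table. Markers of immune cells were higher in LOH as well. They were all 4 listed macrophage or monocyte markers, of which 2 passed, and the 2 listed neutrophil markers, of which 0 passed. Immediate early genes were higher in 12 of 13, of which 8 passed, and Socs3 was listed at 0 in the young and 0.794 in the senescent library. Oxidative phosphorylation genes were lower in all 30 listed members, of which 13 passed, and their median of -0.46 was at percentile 2.31. Markers of the proximal tubule were lower in all 19 listed members, of which 14 passed, with Kap at 202 and 1.54, and the median log2 ratio of these markers was -1.34. The lower oxidative phosphorylation genes and the higher Umod in LOH were not separated from this difference in tubule transcripts.

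In the endo cluster, the 4 genes that passed both thresholds as higher were the immunoglobulin gene Igkc (listed at 0 in the young library and at 1.51 in the senescent library), Jun, Jund and Apoe. Jun, of the AP-1 transcription factor, had means of 1.15 and 13.8, Jund had means of 1.57 and 12.2, and Apoe had means of 3.95 and 11.8. Lower genes included Kap (294 and 4.31), Inmt (3.76 and 0.211) and Gm48281, which was listed at 0.309 in the young and at 0 in the senescent library. Immediate early genes were higher in 12 and lower in 3 of 15 listed members, all 7 listed MHC genes and all 6 listed interferon response genes were higher, and all 10 listed proximal tubule markers were lower. Of these list members, only Jun and Jund among the immediate early genes and Kap among the tubule markers passed the adjusted p in the authors' deposited table. None of the 13 endothelial markers was listed in this cluster.

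In the Marco cluster, all 13 fixed markers of macrophages or monocytes were higher in the senescent library, with a median log2 ratio of 1.90 that lay above all 10000 random lists. Apoe was 15.9-fold higher, at 9.02 and 144, and Ms4a7 was 9.71-fold higher, at 0.423 and 4.10. Antigen presentation genes were higher in all 17 listed members, of which 14 passed the adjusted p in the authors' deposited table, among them H2-Ab1 (14.7 and 81.1), H2-Eb1 (12.7 and 76.0) and their transcriptional activator Ciita (0.159 and 1.29). All 18 listed interferon response genes had higher means, with Ifi27l2a at 1.93 and 19.3, and 11 of them passed. Of 17 listed genes of the senescence-associated secretory list, 13 were higher, and 11 of these passed. The chemokine genes Ccl8, Ccl7 and Cxcl2 were listed at 0 in the young library and at 2.29, 1.61 and 0.985 in the senescent library. The genes with the largest fold changes were Cxcl13, a B cell attracting chemokine, Saa3, an acute phase protein, and S100a8, each listed at 0 in the young library and at 7.14, 6.17 and 4.34 in the senescent library. Immediate early genes were higher in 18 of 21, with Fos at 0.941 and 31.8, and all 45 listed ribosomal protein genes were higher. The largest fold changes downwards were in Slc22a7, Gm48281 and Ces1e, which were listed at 0 in the senescent library. All 19 listed proximal tubule markers were lower, 17 of them past the adjusted p, with Kap at 642 and 2.24. All 48 nuclear-encoded oxidative phosphorylation genes, of which 47 passed, and all 13 genes of the mitochondrial genome were lower as well. Tubule RNA in the young library could lower the young means of the cluster's own genes. The higher lists were not separated from such dilution. Median log2 ratios were 1.61 for MHC, 1.20 for ribosomal protein, 1.09 for secretory and 0.45 for interferon response genes. The macrophage or monocyte markers were at 1.90 and immediate early genes at 1.96.

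The T cluster had higher T cell transcripts in the senescent library, with all 10 listed markers higher and 7 of them past the adjusted p in the authors' deposited table. Cd3d had means of 2.49 and 11.1, Il7r had means of 1.35 and 7.39, and the cytotoxic granule gene Nkg7 had means of 3.32 and 11.9. The chemokine gene Ccl5 was 7.06-fold higher, at 11.9 and 83.8. The largest fold changes upwards were in Junb (0.594 and 10.9), S100a4 (1.16 and 15.6) and S100a6 (2.49 and 24.0). In the B cluster, all 5 listed B cell markers had higher means, 3 of them past the adjusted p, among them Cd79a (11.7 and 24.5) and Ighm (9.61 and 22.6). Their median log2 ratio of 1.10 was at percentile 92.1, inside the range of random lists. Igkc had means of 38.1 and 120.3 in B. Stk17b, Crip1 and Klf2 had the largest fold changes upwards in B, at 15.2-fold, 14.3-fold and 5.34-fold. MHC genes had higher means in all 11 listed members in T, of which 6 passed the adjusted p, and in all 14 in B, of which 8 passed. Ribosomal protein genes were higher in all 46 listed members in T (42 passed) and in all 44 in B (35 passed). Proximal tubule markers were lower in all 20 members in T (19 passed), with Kap at 505 and 2.82, and in all 19 listed members in B (15 passed), with Kap at 499 and 1.24. Oxidative phosphorylation genes were lower in all 46 listed members in T (41 passed) and in all 48 in B (28 passed). As in Marco, the higher lists in T and B were not separated from dilution by tubule RNA in the young library.

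In the Neutro cluster, the neutrophil markers S100a8 and S100a9 were listed as higher, and all 5 listed genes of the mitochondrial genome as lower, with a median log2 ratio of -2.47. None of these passed the adjusted p in the authors' deposited table. The high floor of the young means in Neutro limits these values too.

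**Figure D2:**
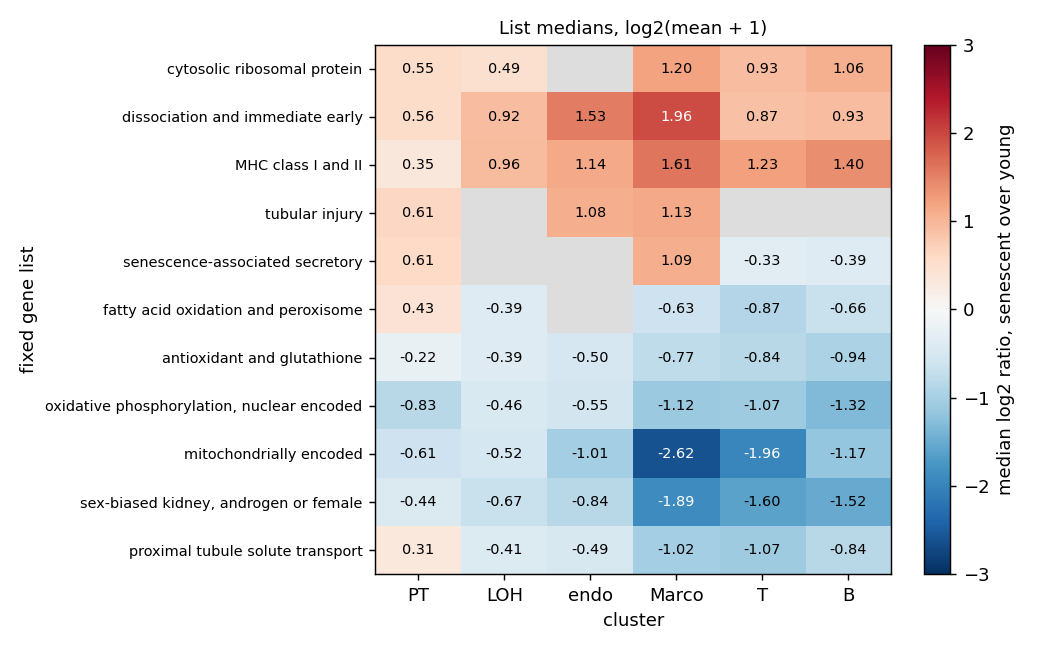
Median log2 ratio of senescent over young, on the log2(mean + 1) scale, for 11 of the 20 functional gene lists (rows) in 6 clusters (columns). Grey cells had fewer than 5 listed members. The list of oxidative phosphorylation genes was below 0 in all 6 clusters, from -0.46 to -1.32, although in endo its median of -0.55 was at percentile 66.5 of random lists and 0 of 10 listed members passed the adjusted p in the authors' deposited table, and the proximal tubule solute transport list was 0.31 in PT and -1.07 in T. The oxidative phosphorylation values in LOH, Marco, T and B were not separated from the lower proximal tubule transcripts there.

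Proximal tubule genes were present outside PT at levels that differed between the libraries. Levels were compared over the genes listed in both PT and the other cluster, so only over genes that differed between the libraries, and the set differs by cluster (29 genes in Marco, 32 in T, 31 in B, 28 in LOH and only 11 in endo). In the young library, the median of these genes was at 110% of the PT level in Marco, 92.5% in T, 77.2% in B, 66.0% in endo and 50.3% in LOH. In the senescent library, the corresponding values were 8.40% in Marco, 8.02% in T, 7.66% in B, 62.4% in endo and 13.8% in LOH. Of the 1051 lower genes of Marco, 806 were also listed in PT, and 450 of these had a higher young mean in PT than in Marco. In T this held for 410 of 677 genes, in B for 267 of 358 and in LOH for 93 of 97. Sharing of direction differed by pair of clusters. Of 2753 genes listed in both Marco and T, 93.2% had the same direction, against 50.9% expected from the share of higher genes in each, and of 1256 genes listed in both PT and LOH, 85.4% had the same direction against 49.9% expected. The shares were lower between PT and the immune clusters, at 67.9% with Marco (49.1% expected), 61.0% with T (47.0% expected) and 59.8% with B (45.0% expected), and between PT and Neutro the share was 34.1% against 35.3% expected. All clusters come from the same pair of libraries, so part of this sharing can come from the libraries themselves. Of the 177 genes listed in all 6 clusters other than Neutro, 41 were higher in all 6 and 103 lower in all 6. The 41 included markers of other cell types, namely Igkc, S100a9, Apoe and the MHC gene H2-Eb1, not all of which passed the adjusted p in each cluster. In PT, for example, Igkc had means of 0.501 and 1.59 and S100a9 had means of 0.313 and 1.13.

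**Figure D3:**
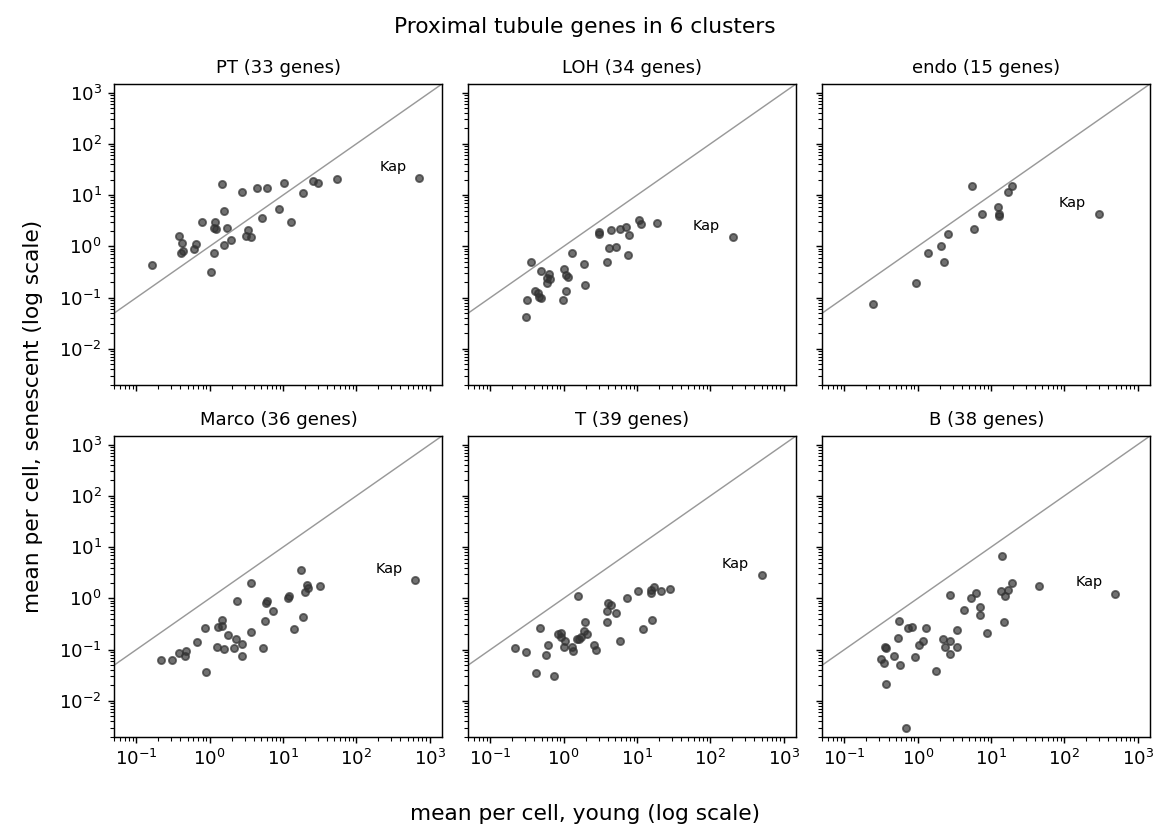
Mean per cell in the young library (horizontal, log scale) and the senescent library (vertical, log scale) of proximal tubule marker and transport genes, one point per listed gene, in 6 clusters. The grey line marks equal means, and means under 0.003 are drawn at 0.003. In PT points lie on both sides of the line, whereas in T every point lies below it, with Kap at 505 and 2.82.

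In the mouse genome build mm10, Kap lies on chromosome 6 from 133849855 to 133853667, Spp1 on chromosome 5 from 104435111 to 104441053, Umod on chromosome 7 from 119462708 to 119479262 and Prlr on chromosome 15 from 10177238 to 10349190. Each of these 4 genes is annotated as protein coding, and each value above is for the whole gene.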

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

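The tests in this part were all chosen after the values they bear on, or values close to them, had been seen. Markers of parietal or injured epithelium had a median log2 ratio of 1.03 in LOH and -2.01 in endo. In LOH 4 of 5 listed members passed the adjusted p in the authors' deposited table, and in endo 0 of 5 did, of which 1 was higher and 4 were lower. The difference of 3.04 was not tested, since there was 1 library per group. Among 206 pairs of clusters with a median for the same list, other medians also had opposite signs, but this was the only pair in which both lay outside the central 95% of their random lists. The tubular injury list, which shares members with these markers, went the other way in endo. Of its 10 listed members there, 6 were higher and 4 lower, with a median of 1.08 at percentile 99.8, and 0 passed. The value of -2.01 thus depends on which members were counted.

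Proximal tubule transcripts were lower in the senescent library in Marco, T and B. A loss in the tubule cells themselves is argued against for solute transport genes, because the log2 ratio in T was lower than in PT for all 24 genes listed in both, with a median difference of -1.37. Of 16 listed proximal tubule markers, 10, Kap among them, were lower in PT too, so part of the loss was seen there. The median log2 ratio of that list was -0.45 in PT, against -2.54 in Marco, -2.16 in T and -2.28 in B. A loss of the size seen in PT would fall short of that in these clusters, although the listed members differ by cluster. Tubule RNA carried into the droplets of other cells in the young library is a candidate source that stays open. A mix with the cell's own RNA would stay below the PT level only if the carried RNA matched the PT cluster's mean. That is not known, so levels relative to PT cannot decide. The median over 29 genes was 109.8% of the PT level in Marco, with quartiles of 74.9% and 136.9% on both sides of 100%. In T and B the medians were 92.5% and 77.2%, also with quartiles on both sides of 100%. In Marco 450 of 806 lower genes listed in both had a higher young mean in PT, so the others did not. Such RNA would dilute the transcripts of the immune cells, and 28 of 28 listed markers of their own class (100%) were higher in the senescent library, although a change with age in these cells stays open and untested. Carried-over RNA in the senescent library stays open too, since Igkc and S100a9, markers of B cells and neutrophils, had higher means there in all 6 clusters other than Neutro, but S100a9 passed the adjusted p of the authors' deposited table in PT and Marco only, and Igkc in all but T. Doublets, free RNA and tubule cells assigned to these clusters could not be separated with means alone. The lower means of oxidative phosphorylation and mitochondrial genome genes in Marco, T and B were not separated from these sources either. Nor were the higher means of MHC and ribosomal protein genes in these clusters, or of interferon response and secretory genes in Marco. In LOH proximal tubule markers were lower too, and the lower oxidative phosphorylation genes there were not separated from these sources.

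Androgen-dependent genes were lower in PT. A senescent library from female mice only is argued against, since 4 of 4 Y-linked genes were detected in it. Their means were also higher in it, with Ddx3y at 0.138 and 0.771 and Kdm5d at 0.0294 and 0.217. That direction carries little weight where 78.4% of listed genes were higher. These genes cannot exclude a library pooled from both sexes, since the number and sex of the mice were not given in the sources used here. Lower androgen signalling in the senescent mice is a hypothesis that may account for the pattern. Of 10 listed genes assigned to a sex from background knowledge after their values were seen, 9 (90%) moved as it requires, the exception being Cyp2e1 at 3.26 and 4.25. The tally was 8 of 9 before Cyp2a4 and Timd2 were added. Cyp2a4 was not listed in PT, so only Timd2 changed the tally. It is 6 of 7 without Kap, Acsm3 and Prlr, which prompted the hypothesis. Of the male-high genes 6 of 7 were lower, and the 3 higher female-high genes add little where 78.4% of listed genes were higher. Slc22a29 of the same list was left out because its side was not known with certainty. Differences in housing, strain or handling stay open, and the contrast name in the authors' deposited table, which sets C57 against WT, does not settle them.

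In PT, 91.1% of the genes past both thresholds in the authors' deposited table were higher in the senescent library. Scaling to a fixed total after the loss of abundant transcripts is argued against as the whole cause, because the loss of all listed lower genes can raise the rest by a log2 factor of at most 1.39 if every cell is scaled to the same total, and 77.0% of the 2881 higher genes (2218) lay above that factor. The 2881 genes were selected at a log2 fold change of at least 1, and the 2218 are a smaller share of all 3948 higher genes listed in PT. An earlier form of this test asked only whether that factor reached 1, and it was replaced because an upper bound cannot show the effect. A larger share of nuclear RNA cannot be told apart from other causes, since the 3 listed nuclear RNAs had a median log2 fold change of 2.59 (Malat1 at 94.2 and 565), while ribosomal protein genes were also higher, with a median of 0.55. The share of higher genes was 99.5% in the lowest and 44.5% in the highest of 5 groups of expression. A change with age stays open.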

How the results depend on the processing

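All 14 counts of higher and lower genes stayed within 1.5 times at an adjusted p of at most 0.01 and with a mean of at least 0.1 in the higher library. No list median changed its sign under any of the 4 alternatives, for 105 medians. Medians moved by more than the SD of their members in 35 cases with a pseudocount of 0.1, in 50 with 0.01 and in 51 with the log2 fold changes of the authors' deposited table, and in none without the filter on low values, since a smaller pseudocount widens the ratios of low genes by construction.

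The counts below are from the authors' deposited table. At an absolute log2 fold change of at least 2, there were 1155 higher and 51 lower genes in PT, 21 and 58 in LOH, 683 lower in Marco, 39 higher and 587 lower in T and 7 higher in B. At 0.25, which is under the smallest value listed, there were 1089 lower genes in PT, 83 higher in LOH and 289 higher in T. The other settings were chosen after seeing the data. Without an adjusted p, there were 485 higher and 372 lower genes in LOH, 426 and 348 in endo, 2124 higher in Marco, 1129 and 1701 in T, 501 and 1665 in B and 20 and 353 in Neutro. Higher genes then outnumbered lower ones in LOH and endo, the reverse of the main counts, so the balance there depends on the adjusted p. Without genes whose mean was higher in PT, lower genes numbered 28 in LOH, 0 in endo, 601 in Marco, 493 in T and 210 in B, and 1 higher gene was left in endo. These changes follow from the construction of each setting, which admits or removes genes.

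No paired analysis was possible because each group had 1 library and no test between groups was run. The alternatives planned for counts per cell (scaling by median of ratios, totals without mitochondrial genes, UMI minima, barcode filters, thinning, clustering resolution, doublet removal) and those for cluster identities were not run, because the values analysed were means per cluster. Depth per library is unknown, so precision could not be given.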

Other observations

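Pathway annotations in the authors' deposited table were summarised for PT and Marco, for pathways with at least 15 listed genes, a choice made after the data were seen. Of 247 pathways in PT, 50 had a median log2 ratio above the central 95% of 10000 random lists and 21 below it, and pathways share genes. The listed genes counted here need not pass the adjusted p, and 78.4% of all listed genes were higher in PT and 58.3% in Marco. In PT, proteasome genes were lower in 21 and higher in 4 of 25 listed genes, with a median of -0.50 at percentile 0.01. All 29 listed genes of IL-17 signalling and all 38 of TNF signalling were higher in PT, with medians of 0.42 and 0.31. Hippo signalling genes were higher in 61 of 62, at percentile 99.99, and retinol metabolism genes in 13 of 18, a share below that of all listed genes, with a median of 0.47 at percentile 99.9. Genes of the peroxisome were higher in 29 and lower in 25 in PT (percentile 10.8), those of fatty acid metabolism in 17 and 14 (percentile 5.44) and those of fatty acid degradation in 16 and 10 (percentile 68.8).

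Of 250 pathways in Marco, 103 had a median above the central 95% and 49 below it. Chemokine signalling genes were higher in 77 of 83, Toll-like receptor signalling genes in 38 of 39 and phagosome genes in 64 of 76. All 25 listed genes of the citrate cycle were lower in Marco, with a median of -0.75, and fatty acid degradation genes were lower in 30 of 35. Retinol metabolism genes were lower in Marco in 15 of 16, and the difference from PT was not tested. Proximal tubule markers were lower in Marco too, and the medians were not computed without genes of the proximal tubule.

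Genes that were higher in PT had a median genomic span of 35.6 kb and those that were lower a median of 8.87 kb, with a span for 99.1% of the listed genes. The corresponding values were 28.3 and 14.0 kb in LOH, 26.9 and 17.3 kb in endo, 22.8 and 20.5 kb in Marco, 22.4 and 21.4 kb in T, 17.1 and 17.9 kb in B and 4.15 and 22.5 kb in Neutro.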
